A study of Homo sapiens with 4 samples.

How the data were processed

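RNA of Huh7, an established human hepatoma cell line, was measured on 4 single-colour (Cy3) Agilent 44K expression arrays, 2 from cells overexpressing R-spondin2 and 2 from the negative control, grouped by the sample titles. The labels do not say whether the 2 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The extraction protocol in the labels describes a blood RNA kit with globin reduction although the sample is named as Huh7, so markers of blood cells were among the gene lists tested.

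Per the file headers, each array was extracted with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name Agilent Feature Extraction 9.1. The deposited intensity values are background-subtracted signals per spot with spatial and multiplicative detrending and surrogates for signals near background, not normalized between arrays, per the file headers. The mean pixel intensity of each spot and the median intensity around it are deposited beside them. The authors also deposited a table of log2 values with 1 value per probe. All 4 of its columns have a median of 7.45 and the same distribution, so the values are quantile-normalized, and each column follows log2 of the processed signal of its array with a correlation across probes of 0.9999 or more after rounding. How that table was made is not given in the sources used here. The genome build of the probe coordinates is not named in the files.

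From the scanner files, log2 of the processed signal was taken and the array's 75th percentile over the 43376 non-control spots was subtracted. Control spots and spots with outlier flags (58 to 117 per array) were left out, and no spot was saturated. Spots of the same probe were averaged, which concerned 264 probes printed repeatedly. Of 41000 probes, 31683 were well above background on both arrays of at least 1 group and had a value on every array. A gene, meaning a distinct gene name in the files, was represented by its brightest tested probe, which left 22537 genes. Gene names are those of the array design. Against a table of RefSeq genes on assembly GRCh38.p14, used only for names, 14841 genes matched by accession, 671 by symbol and 165 by an older symbol, and 6860 kept the name in the file.

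Groups were compared with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over the genes tested. Log2 fold changes are overexpression minus control and are given with the standard error of the fit, n = 2 arrays per group. Where a probe was not well above background on 1 or both arrays of a group, as for RSPO2 and for the genes given with "at least", a lower bound of the fold was computed from the bright group's mean and the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. A total of 29 gene lists holding 832 genes were fixed, of which 755 genes were tested. Each list was compared with all other genes by camera with a preset inter-gene correlation of 0.01, and beside it by camera with an estimated correlation and by fry. Named genes were chosen by a fixed rule: RSPO2 with every probe, up to 12 genes per direction past the threshold with an official symbol, well above background on every array and with groups that did not overlap, up to 4 genes per direction past the threshold with a bound, and for each list up to 4 members past the threshold or, where none passed, the 2 members with the highest mean signal. Genes outside this rule, including list members past the threshold only when adjusted over the list alone, were chosen after their values were seen. The groups, lists, tests and all alternatives except those said to be added later were fixed before the data were examined.

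The gene test was checked on simulated data with 22537 genes, in which 200 genes of known fold change were set in each of 10 simulations of overexpression against control. Of changes of 0.5 on the log2 scale it called 1.4%, of 2-fold changes (log2 size 1) 67.6%, of log2 size 2 94% and of log2 size 3 97%, with 5.3 false calls per simulation. With an intensity trend in eBayes it called 56.8%, 83.6%, 98.6% and 99.8% of these sizes, with 11.3 false calls per simulation. The simulated variances were drawn from the intensity-trend fit to these arrays. That fit is favoured by construction, so the comparison does not show that it has more power on the real data. Camera with the preset correlation called a simulated list of 25 genes shifted by 0.2 in 100% of 20 simulations and 1 of 560 unchanged lists. Camera with an estimated correlation called that shifted list in 0% of them, so with 2 residual degrees of freedom it had no power for a shift of this size. Simulated genes were independent and lists were drawn at random, a setting that favours a small preset correlation. False calls may be more frequent on real lists of correlated genes, which were not simulated.

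Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the authors' log2 values, no filter on dim probes, a stricter filter, flagged spots kept, each probe on its own, the mean of a gene's probes, an intensity trend in eBayes, no moderation of the variances, the replicate number as a block, each array left out, and an adjusted p of 0.01. Scaling by the labelling spike-in spots, a crossed pairing of replicates and the intensity trend on other normalizations were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.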

Results

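The experiment compared gene expression between Huh7 hepatoma cells that overexpressed R-spondin2 and their negative control. R-spondin2, encoded by RSPO2, is a secreted protein that binds LGR receptors and raises the response of cells to Wnt ligands. There were 2 arrays per group, and this number limits the precision. Between 77.8% and 79.9% of the non-control spots of an array were well above background, and the median signal was 207 and 191 scanner units on the control arrays and 180 and 204 on the overexpression arrays. Correlations across genes were 0.998 within both groups and 0.996 to 0.997 between groups. Between single arrays, 121 genes differed by at least 2-fold within the controls and 57 within overexpression, against 122 to 197 between groups. All 4 arrays lay on 1 slide, with the overexpression samples at positions 1 and 2 and the controls at positions 3 and 4. Array position and group therefore cannot be told apart.

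The RSPO2 transcript was far more abundant in the overexpressing cells. The probe A_23_P258294 (chromosome 8, 108970317 to 108970376 in the coordinates of the array files, build not named) gave signals of 299000 and 329560 on the overexpression arrays and ranked 32 and 31 among all probes. On the control arrays it gave 31.6, well above background, and 8.41, not well above background. The overexpression arrays were 10500-fold and 10660-fold above control array 1. With the signal of control array 2 raised to the lowest level well above background, RSPO2 was at least 19040-fold higher on average. The fitted log2 fold change of RSPO2 was 14.27 ± 0.63 (SE, n = 2 per group) and includes the signal that was not well above background. It was 11.99 with normexp background correction. Because the control arrays differed from each other, the limma adjusted p was 0.057, and it was 2.1e-05 with an intensity trend in eBayes. The other RSPO2 probe, A_23_P430930 (chromosome 8, 108911680 to 108911739), was not well above background on any array, with signals of 2.56 to 3.90. Probes for RSPO1 were not well above background either, and the RSPO3 probe that was detected gave 76.9 to 81.8 on all arrays.

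**Figure D1:**
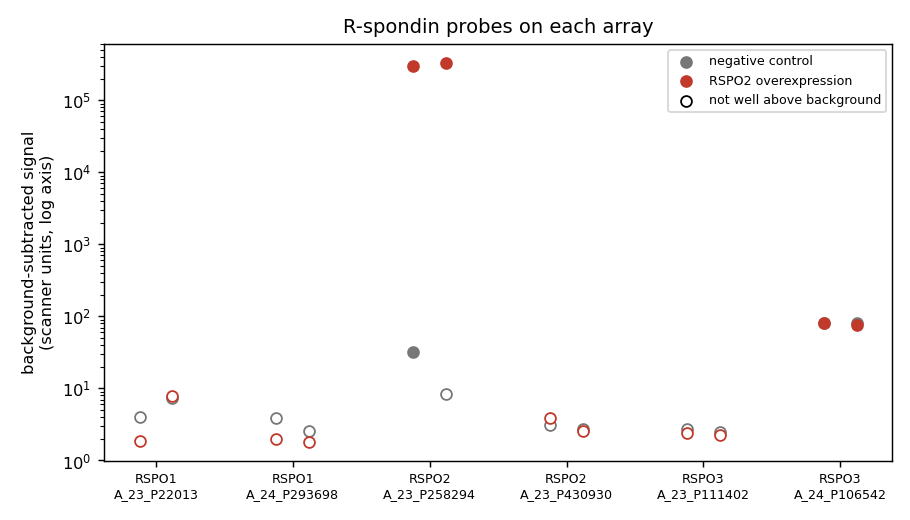
Background-subtracted signal in scanner units (vertical log axis) of each R-spondin probe (horizontal axis) on the 2 negative control arrays (grey) and the 2 RSPO2 overexpression arrays (red), with open circles for signals not well above background. One RSPO2 probe reached 299000 and 329560 in overexpression against 31.6 and 8.41 in the controls, and the other RSPO2 probe stayed between 2.56 and 3.90 on all 4 arrays.

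The largest difference past the threshold was in HSPA6, which encodes a stress-inducible HSP70 chaperone. HSPA6 rose 9.08-fold (log2 fold change 3.18 ± 0.06, limma adjusted p = 0.011), from a signal of 15.4 to 140. HKDC1, which encodes a hexokinase-like enzyme, rose 4.03-fold (2.01 ± 0.06, adjusted p = 0.018), from 60.8 to 245, and a second HKDC1 probe gave 1.30 ± 0.09. The transcript THC2655314, which has no gene symbol in the files (probe on chromosome 6, 54487178 to 54487237), was not well above background in the controls and was at least 1.94-fold higher in overexpression (adjusted p = 0.018). Its fitted log2 fold change was 1.99 ± 0.05. These sizes hold for the processed signals: with normexp background correction, which adds an offset to every signal, the log2 fold changes were 1.22 for HSPA6 and 1.33 for HKDC1, both still past the threshold. THC2655314 lost its call, at 0.30 (adjusted p = 0.27). The HSPA6 probe lies on chromosome 1 (161496158 to 161496217) and the HKDC1 probe on chromosome 10 (71026958 to 71027017).

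These 3 genes were the ones past an adjusted p of 0.05 by limma among 22537 genes tested. All 3 were higher in overexpression, by at least 2-fold in the fitted values, and 0 genes were lower. At an unadjusted p under 0.05 there were 2352 genes, 1107 higher and 1245 lower, against 1127 expected by chance. Some genes just short of the threshold were named after their values were seen. TNFRSF9, a TNF receptor family member, was at least 3.06-fold higher (adjusted p = 0.057), IFNA8 at least 2.33-fold (adjusted p = 0.057) and CRX at least 2.08-fold (adjusted p = 0.061), all from controls not well above background. RGS16, a regulator of G protein signalling, was 2.06-fold higher (adjusted p = 0.077). With normexp the log2 fold changes were 0.39 for TNFRSF9 (adjusted p = 0.13), 0.23 for IFNA8 (0.38), 0.29 for CRX (0.25) and 0.90 for RGS16 (0.0050). By size alone, 60 genes were at least 2-fold higher and 19 at least 2-fold lower, of which 54 and 19 were in the dimmest tercile by signal. The count of calls depended on the variance model, the filter on dim probes and single arrays. It was 124 (115 higher, 9 lower) with an intensity trend, 46 with normexp, which shared 2 of the 3 genes, and 0 without moderation of the variances. With no filter on dim probes it was 0 as well, with HSPA6 (adjusted p = 0.18), HKDC1 (0.20) and THC2655314 (0.20) at the log2 fold changes given above. It was 0 without overexpression array 1 and 0 without overexpression array 2, and without either control array the 1 gene past the threshold was RSPO2. With scaling by spike-in spots, which moved the median of all genes to -0.16, 138 genes were higher and 241 lower. The log2 spike-in level above the 75th percentile was 1.665 and 1.812 on control arrays 1 and 2. On overexpression arrays 1 and 2 it was 1.962 and 1.813. Replicates thus differed about as much as the groups, so this shift does not show a broad decrease.

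Genes of the unfolded protein response, which encode chaperones and degradation factors of the endoplasmic reticulum, were higher in overexpression as a group. All 25 tested members had a positive log2 fold change, with a median of 0.20, and the list rose against all other genes (camera adjusted p = 1.8e-13; adjusted p = 0.64 with an estimated correlation). Fry, which does not compare a list with other genes, did not call this list. Over all genes 0 of its members passed the threshold, and adjusted over the list alone 12 passed, all higher. Here and for the other lists, members named because they passed adjusted over the list alone were chosen after their values were seen. Over all lists these were 34 members, of which 4 to 10 still passed that way with 1 array left out, 22 without the filter on dim probes and 28 with normexp. Among them, chosen after their values were seen, were MANF (0.51 ± 0.08), DNAJC3 (0.48 ± 0.09), SDF2L1 (0.42 ± 0.08), HSPA5, the main chaperone of the endoplasmic reticulum (0.32 ± 0.06), DNAJB9 (0.32 ± 0.06) and HERPUD1 (0.31 ± 0.06). The 2 brightest members were SEC61B (0.04 ± 0.05) and XBP1 (0.10 ± 0.05). The list's median relative to each gene's mean was -0.15 and -0.08 on the control arrays and 0.12 and 0.10 on the overexpression arrays. With the mean of a gene's probes in place of the brightest probe the median was 0.12. With spike-in scaling 15 of the 25 members were positive and the median was 0.05, against -0.16 for all genes.

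Heat shock protein genes rose as a list as well (22 of 24 positive, median 0.08, or -0.06 with spike-in scaling, camera adjusted p = 2.1e-07; adjusted p = 0.64 with an estimated correlation). Besides HSPA6, past the threshold over all genes, DNAJB4 (0.44 ± 0.06) and HSPA1A (0.40 ± 0.06) passed adjusted over the list alone. Genes of the ATF4 and amino acid response, which is switched on when translation initiation is inhibited, rose as a list (20 of 31 positive, median 0.03, or -0.12 with spike-in scaling, camera adjusted p = 0.014; adjusted p = 0.64 with an estimated correlation). Its 0 members past the threshold over all genes became 4 adjusted over the list alone, all higher and named after they were seen: ATF3 (0.77 ± 0.06), a transcription factor of stress responses, PPP1R15A (0.73 ± 0.09), which restores translation after stress, DDIT3 (0.60 ± 0.06), which encodes CHOP, and CTH (0.49 ± 0.06). The brightest members were ATF4 (0.03 ± 0.07) and TRIB3 (0.05 ± 0.06). Relative to each gene's mean, the ATF4 list's median was -0.028 and -0.0075 on control arrays 1 and 2. On overexpression arrays 1 and 2 it was -0.0081 and 0.045, so the array medians of the groups overlapped although camera called the list. The spike-in medians of both lists are to be read against -0.16 for all genes. The ATF4 list missed the threshold without control array 1 (adjusted p = 0.13), without overexpression array 2 (adjusted p = 0.24) and with spike-in scaling (adjusted p = 0.13).

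Ribosomal protein genes were the other list past the threshold (45 of 50 positive, camera adjusted p = 0.0046; adjusted p = 0.64 with an estimated correlation). Their median was only 0.03, with RPS2 at 0.07 ± 0.06 and RPL13 at 0.03 ± 0.05, and 0 members passed over all genes or adjusted over the list alone. The median turned to -0.017 with quantile normalization and to -0.011 with the authors' values. With spike-in scaling it was -0.12, but there the median of all genes was lower still, at -0.16. The call was also lost without control array 1 (adjusted p = 0.13). In total 4 of the 29 lists passed by camera, all of them higher, 0 with an estimated correlation, and by fry, which does not compare a list with other genes, 1 (YAP/TEAD targets).

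**Figure D2:**
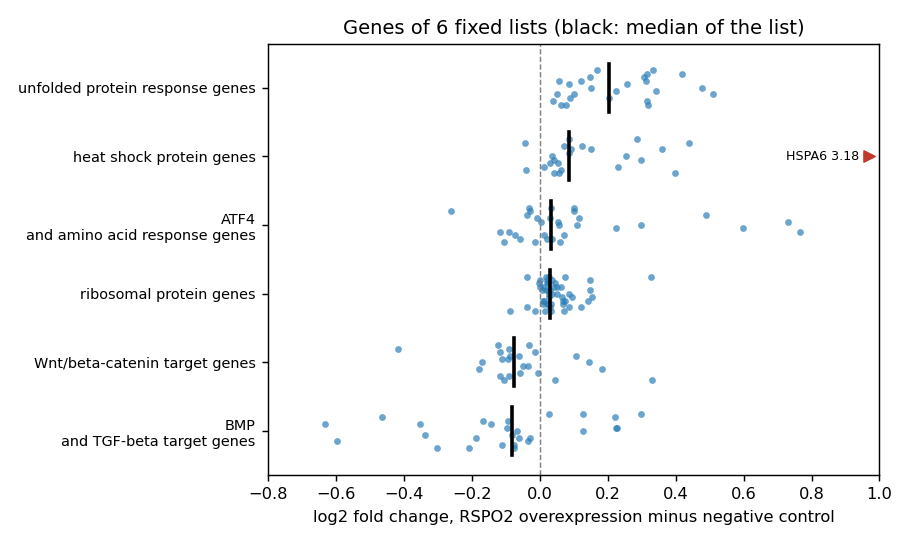
Log2 fold change of each tested gene (points, horizontal axis, mean of 2 overexpression minus mean of 2 control arrays) in 6 of the fixed gene lists, with the list's median as a black bar and HSPA6 drawn at the right edge with its value. All 25 unfolded protein response genes lie above 0 with a median of 0.20, while 19 of 24 Wnt/beta-catenin target genes lie below 0 with a median of -0.08.

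Target genes of Wnt/beta-catenin signalling, the pathway that R-spondins amplify, did not pass the test as a list. Of 24 tested targets 5 had a positive and 19 a negative log2 fold change, with a median of -0.08 (camera adjusted p = 0.21), and 0 passed over all genes or adjusted over the list alone. The brightest were SOX4 (-0.06 ± 0.07) and DKK1 (-0.09 ± 0.07). Values of the feedback targets, named after they were seen, were -0.06 ± 0.09 for AXIN2, -0.09 ± 0.05 for ZNRF3, -0.11 ± 0.05 for RNF43, -0.04 ± 0.17 for LGR5 and -0.42 ± 0.11 for SP5, and MYC was at 0.33 ± 0.07. AXIN2 and LGR5 were dim, with control signals of 110 and 23.3. Among 49 Wnt and R-spondin receptors and signal transducers the median was -0.06 (adjusted p = 0.14), with WNT6 at 0.10 ± 0.10 and GSK3A at -0.05 ± 0.06, and SFRP4 (0.68 ± 0.08) was the 1 member past the threshold adjusted over the list alone. With normexp SFRP4 was at 0.14 and did not pass (list-alone adjusted p = 0.44). Of the liver zonation genes, the pericentral list, which Wnt signalling maintains in liver tissue, had a median of -0.04 (15 tested, adjusted p = 0.65; ALDH1A1 -0.04 ± 0.06, GSTM3 -0.08 ± 0.06) and the periportal list -0.03 (15 tested, adjusted p = 0.97; SDSL -0.03 ± 0.12, NAGS -0.13 ± 0.07).

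Among targets of BMP and TGF-beta, 20 of 27 were negative, with a median of -0.08 (camera adjusted p = 0.069), and 0 members passed over all genes or adjusted over the list alone. The brightest were ID1 (-0.11 ± 0.05) and TGFBI (-0.10 ± 0.06). Named after they were seen, ATOH8 (-0.63 ± 0.13), HAMP, the gene of the iron hormone hepcidin (-0.46 ± 0.09), SMAD9 (-0.35 ± 0.08), SMAD6 (-0.34 ± 0.09) and SMAD7 (-0.30 ± 0.07) were among the lowest. This list passed with median scaling (adjusted p = 0.036), normexp (0.0052), the authors' values (0.048), the mean of probes (0.036) and without control array 2 (0.027). YAP/TEAD targets had a median of -0.08 (23 tested, 18 negative, camera adjusted p = 0.21, fry adjusted p = 0.047), with DLC1 at -0.07 ± 0.06 and CYR61 at -0.09 ± 0.05, and GADD45A (0.62 ± 0.07) passed adjusted over the list alone. Epithelial-mesenchymal transition genes stayed near 0 (28 tested, median -0.03, adjusted p = 0.95; VIM 0.01 ± 0.06, KRT18 -0.06 ± 0.07), with ZEB1 (0.66 ± 0.06) past the threshold adjusted over the list alone at a control signal of 28.6. With normexp ZEB1 was at 0.27 and did not pass (list-alone adjusted p = 0.087).

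Hepatocyte identity and growth genes did not pass as lists. Secreted proteins and liver transcription factors had a median of -0.04 (30 tested, adjusted p = 0.63; ALB -0.01 ± 0.06, TF 0.07 ± 0.06; SERPINC1 at 0.59 ± 0.08 passed adjusted over the list alone, but not with normexp, at 0.28). Progenitor and hepatoma stem cell markers had a median of -0.04 (21 tested, adjusted p = 0.66; KRT19 -0.09 ± 0.05, ALDH1A1 -0.04 ± 0.06), with SOX2, not well above background in the controls, past the threshold adjusted over the list alone, but not with normexp (0.12). G1/S and replication genes were negative in 29 of 32 members with a median of -0.04 (adjusted p = 0.076; MCM7 -0.07 ± 0.05, TK1 0.01 ± 0.05), and this list passed, as lower, with quantile normalization (0.041), normexp (0.012) and the authors' values (0.048). G2/M genes had a median of -0.03 (32 tested, adjusted p = 0.50; PTTG1 0.02 ± 0.05, BIRC5 0.01 ± 0.05). In metabolism, the medians were -0.02 for cholesterol biosynthesis (25 tested, adjusted p = 0.66; EBP -0.03 ± 0.05, FDPS -0.0041 ± 0.058) and -0.02 for fatty acid and triglyceride genes (34 tested, adjusted p = 0.96; FADS2 -0.04 ± 0.07, SCD -0.02 ± 0.06). They were -0.02 for hypoxia and glycolysis (34 tested, adjusted p = 0.87; GAPDH 0.03 ± 0.06, LDHA 0.01 ± 0.06) and 0.01 for oxidative phosphorylation (38 tested, adjusted p = 0.66; COX6A1 0.03 ± 0.06, COX7A2 0.01 ± 0.07). Hypoxia and glycolysis genes passed, as higher, without overexpression array 1 (0.038).

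The other stress and inflammation lists did not pass either. NF-kappaB and acute phase genes had a median of 0.05 (29 tested, adjusted p = 0.12; ORM1 -0.13 ± 0.07, ORM2 -0.13 ± 0.07), and adjusted over the list alone IL8 (0.41 ± 0.05), TNFAIP3 (0.43 ± 0.06) and RELB (0.56 ± 0.09) passed as higher and HAMP as lower. This list passed with normexp (adjusted p = 0.026) and with the mean of probes (0.036). Immediate early genes and MAPK feedback had a median of -0.05 but a camera direction upward (32 tested, adjusted p = 0.64; IER2 0.02 ± 0.06, JUN 0.23 ± 0.06), with NR4A3 (0.76 ± 0.06), EGR2 (0.58 ± 0.08) and FOSL2 (0.37 ± 0.06) past the threshold adjusted over the list alone. With normexp these were at 0.44, 0.29 and 0.19, and FOSL2 did not pass. Interferon-stimulated genes had a median of -0.03 (31 tested, adjusted p = 0.66; ISG15 -0.05 ± 0.06, ISG20 0.28 ± 0.06), and p53 targets -0.02 (27 tested, adjusted p = 0.87; BBC3 0.05 ± 0.09, GDF15 0.06 ± 0.06; GADD45A past the threshold adjusted over the list alone). Metallothionein and NRF2 genes had a median of 0.05 (31 tested, adjusted p = 0.14; FTH1 0.05 ± 0.05, FTL 0.03 ± 0.05). They passed with normexp (0.026) and without overexpression array 2 (0.028).

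Markers of other cell types did not pass as lists. This test compares the groups, so it cannot show whether blood RNA was present in both. By control signal, the 2 brightest leukocyte markers, CD79A and CD14, gave 2665 and 1704. The brightest erythroid genes, SLC4A1 and HBA1, gave 84.2 and 85.8. For comparison, KRT19 and ALDH1A1, the brightest progenitor markers, gave 199750 and 74893. Leukocyte markers had median signals of 71.2 in controls and 78.6 in overexpression (17 tested, median 0.03, adjusted p = 0.65; CD79A 0.04 ± 0.09, CD14 -0.0020 ± 0.13), and erythroid and globin genes 39.5 and 42.5 (13 tested, median -0.02, adjusted p = 0.88; SLC4A1 0.28 ± 0.16, HBA1 -0.02 ± 0.15). Endothelial markers had a median of -0.03 against a positive mean (11 tested, adjusted p = 0.50; EGFL7 -0.08 ± 0.05, CLDN5 0.29 ± 0.19); LYVE1, not well above background in the controls and at least 1.90-fold higher in the processed signals, passed adjusted over the list alone. With normexp its log2 fold change was 0.34 and it did not pass (list-alone adjusted p = 0.062). Fibroblast and stellate cell markers had a median of -0.08 (15 tested, adjusted p = 0.12; LUM -0.20 ± 0.05, FBLN1 -0.06 ± 0.06), with DES (-0.47 ± 0.07, or -0.29 with normexp) past the threshold adjusted over the list alone. That list passed, as lower, without overexpression array 1 (0.038). The endothelial list passed with spike-in scaling (0.0011), with an upward camera direction although its median of -0.17 lay near that of all genes. Cholangiocyte markers had a median of -0.06 (13 tested, adjusted p = 0.28; KRT19 -0.09 ± 0.05, ANXA4 -0.06 ± 0.09).

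With an intensity trend in eBayes, which lets bright genes have a smaller prior variance, 124 genes passed, and the 3 genes above were among them. They held 7 unfolded protein response genes of 25 tested (Fisher's exact test, 1-sided, adjusted p = 1.7e-09 over the 29 lists) and 4 ATF4 genes of 31 (adjusted p = 3.6e-04), but 2 heat shock genes of 24 (adjusted p = 0.074) and 0 Wnt/beta-catenin targets of 24. Fisher's test takes genes as independent, and camera with an estimated correlation gave an adjusted p of 0.64 for the first 3 of these lists. Named after they were seen, genes past this threshold included FBXO32 (0.97), CAPN2 (0.92), AGR2, a disulfide isomerase family member of the endoplasmic reticulum (0.83), and FICD, which modifies HSPA5 (0.57). MDGA1 (-0.71), ATOH8 (-0.63) and ERBB3 (-0.30) were among the 9 lower ones. Also named after they were seen, the zinc finger genes ZNF554 (0.89 ± 0.07, SE of the trend fit), ZNF555 (0.63 ± 0.06), ZNF556 (0.95 ± 0.12, or 0.45 with normexp), ZNF57 (0.47 ± 0.06) and ZNF77 (0.62 ± 0.05) passed with adjusted p of 0.0039 to 0.020. In the main fit, which has no trend, none of them passed, with limma adjusted p of 0.16 to 0.24. With normexp background correction and no trend, ZNF554, ZNF555 and ZNF77 passed. These 5 genes follow one another on chromosome 19, with probes between 2834881 and 2933493 in the array files' coordinates, and the 5 measured genes on each side had log2 fold changes of -0.14 to 0.08.

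**Figure D3:**
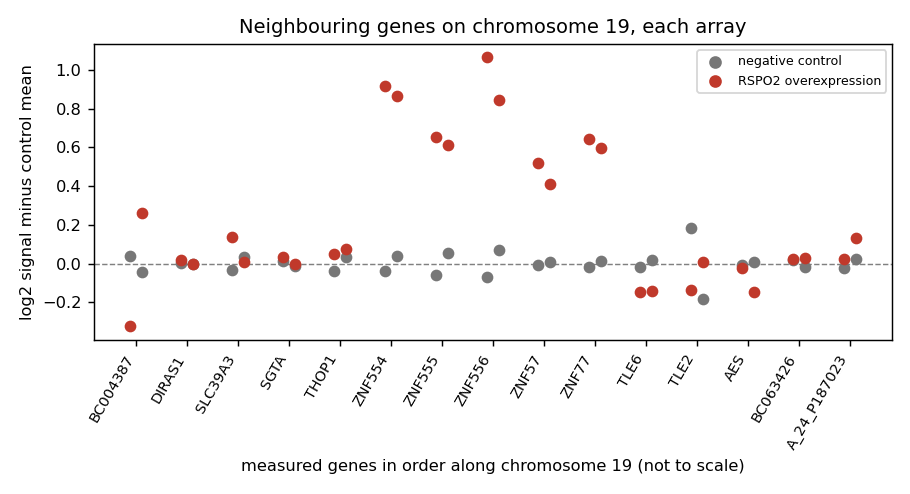
Log2 signal of 15 measured genes in their order along chromosome 19 (horizontal axis, not to scale), minus the mean of the control arrays for each gene (vertical axis), with each negative control array in grey and each RSPO2 overexpression array in red. Both overexpression arrays lie above both control arrays for ZNF554, ZNF555, ZNF556, ZNF57 and ZNF77, by 0.47 to 0.95 on average, and the flanking genes average between -0.14 and 0.08.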

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

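Scaling by spike-in spots, the crossed pairing and the intensity trend on other normalizations were chosen after seeing the data; the other alternatives were planned. The 3 genes past the threshold were the same genes with quantile normalization, median scaling, the authors' values and flagged spots kept. Of 2045 values of named genes compared across the settings, 96 had the other sign, none of them for a gene past the threshold on either side. The 2045 include settings that cannot change a sign: the intensity trend, no moderation, the replicate block, an adjusted p of 0.01 and each probe on its own. With either change of the filter on dim probes no sign changed. The most changes were 23 of 114 named genes with spike-in scaling and 15 of 114 with quantile normalization. The unfolded protein response and heat shock lists passed, as higher, under every normalization and filter with the standard variance model, with the mean of probes, with the replicate block and without each array. Neither passed with an estimated correlation, which called 0% of simulated lists of independent genes shifted by 0.2. Fry, which tests whether a list's genes differ between the groups without comparing them with other genes, called neither. The lists were not run with each probe on its own, without moderation, at an adjusted p of 0.01, with the crossed replicate block or with the intensity trend on other normalizations. Their group medians, taken relative to the median of all genes, ranged from 0.13 to 0.26 and from 0.08 to 0.12. Signal over background limits the dim genes: within-group SDs had a typical size of 0.14 in the dimmest tercile and 0.05 in the brightest.

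Normexp gave 46 genes (45 higher, 1 lower), 6 list genes, 8 lists and an RSPO2 log2 fold change of 11.99, now past the threshold. HSPA6 (1.22) and HKDC1 (1.33) stayed past it with smaller log2 fold changes, and THC2655314 lost its call (0.30, adjusted p 0.27). Of 56 named genes with a log2 fold change of at least 0.25 in size, 16 were smaller by over 1.5 times and 0 had the other sign. By construction the offset shrinks the folds of dim genes. Of 34 list members past the threshold adjusted over the list alone, 28 still passed that way, and SFRP4, LYVE1, ZEB1, SERPINC1, FOSL2 and SOX2 did not. Spike-in scaling left 9 of the 34. With no filter on dim probes 0 genes passed, 0 of them 2-fold, and 0 list genes, although HSPA6 (3.18), HKDC1 (2.01) and THC2655314 (1.99) had unchanged log2 fold changes (adjusted p of 0.18, 0.20 and 0.20). The mean of probes gave 7 genes, all higher and 2-fold, with RSPO2 (14.27) just past the threshold at an adjusted p of 0.0498. The intensity trend gave 124 genes (115 higher, 9 lower, 24 of them 2-fold), 18 list genes and RSPO2 (14.27) at 2.1e-05. On quantile-normalized values the trend gave 126 genes (116 higher, 10 lower, 25 of them 2-fold) and 19 list genes, on spike-in scaled values 130 (70 higher, 60 lower, 53 of them 2-fold) and 7 list genes, and on normexp values 170 (143 higher, 27 lower) and 28 list genes. Without moderation of the variances there were 0 genes, 0 higher, 0 past 2-fold and 0 list genes, although 2007 genes had an unadjusted p under 0.05. An adjusted p of 0.01 left 0 genes in each of these counts. Spike-in scaling gave 379 genes (138 higher, 241 lower, 80 of them 2-fold), 13 list genes and RSPO2 (14.12) past the threshold. It moved the median of all genes to -0.16, a shift about as large as the difference between replicates in spike-in level. Relative to that shift the unfolded protein response list stood at 0.22 and the heat shock list at 0.10. With camera's estimated correlation 0 lists passed and with fry 1. The ribosomal list's median reversed to -0.017 with quantile normalization and -0.011 with the authors' values. For the other changes the cause was not tested.

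Leaving out each array in turn gave 0 to 1 genes past the threshold, 0 to 1 higher, 0 to 1 past 2-fold and 0 list genes, since a group of 1 array leaves 1 residual degree of freedom less and the lone array is assumed to vary like the other group. The RSPO2 log2 fold change ranged from 13.37 to 15.17, with adjusted p of 8.5e-04 to 0.58, and 2 to 6 lists passed. None of the 3 genes passed without any one array: HSPA6 had log2 fold changes of 3.14 to 3.23 with adjusted p of 0.10 to 0.31, HKDC1 1.98 to 2.04 and THC2655314 1.98 to 2.01, both with adjusted p of 0.14 to 0.47. The replicate numbers did not pair the samples: deviations of same-numbered arrays had a correlation of -0.11 across genes. The replicate block gave 0 genes, 0 higher, 0 past 2-fold and 0 list genes, with 1880 genes at an unadjusted p under 0.05, and 4 lists past the threshold. The crossed replicate block gave 0 genes, 0 higher, 0 past 2-fold and 0 list genes, with 2371 genes at an unadjusted p under 0.05.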

Other observations

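The tests in this part were chosen after the results they bear on had been seen, except the comparison of probe sequences. Of the 29 list medians, 6 lay below the 2.5th percentile of brightness-matched random lists and 5 lay equally far out on the high side, 11 in all, against 1.45 expected if genes were independent and no list shifted. These percentiles do not separate shifts of the lists from correlation between genes of a list. The Wnt/beta-catenin targets lay at the 0.63rd percentile. The ribosomal list, with a median of 0.03, lay at the 43.5th percentile of lists of equally bright genes, so its camera call was not separable from the level of bright probes in general. Among 21874 genes well above background on all arrays, 20 were at least 2-fold higher and 1 was at least 2-fold lower. The other 2 ways of splitting the 4 arrays into pairs gave 0 genes past the threshold each, against 3 for the real one. With 3 splits in all, no share under 0.05 can be reached.

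The run of 5 zinc finger genes on chromosome 19 stood out from all other neighbours, under the intensity trend. In 2000 shuffles of 21870 genes along the genome, none held 5 neighbours whose weakest member had a moderated statistic as far from 0 as 7.61 (permutation p = 5e-04, the smallest these shuffles can give). The highest shuffle reached 3.26, the best run elsewhere in the real data 2.60 and the other splits of the arrays 1.97. A change of the whole family does not account for it. The other 205 ZNF genes of chromosome 19 had a median log2 fold change of 0.0238 (113 higher, 92 lower), against 0.63 for the run. The run's median lay between 0.48 and 0.69 under the alternatives, or between 0.59 and 0.70 relative to the median of all genes. The median of the 205 genes does not exclude a change of some zinc finger genes. Named after they were seen, ZNF432 (0.89), ZNF473 (0.42), ZNF251 (0.46) and ZFP2 (1.57), outside the run, passed as higher with the intensity trend. No gene named ZNF passed as lower. Whether these genes share a cause with the run was not tested. Probes of different genes in the run shared at most 10 bases in a row, which leaves open that a transcript binds several of them elsewhere, as transcript sequences were not searched. A local event in the overexpressing cells, such as an insertion, a copy gain or a shift in the clones that make up the culture, may have raised these neighbours together, and this was not tested; a check of the genomic DNA would be needed.

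The unfolded protein response genes may be higher because the cells were making a large amount of a secreted protein, a hypothesis that a control expressing another secreted protein would test and that was not tested here. Their median lay above all 10000 brightness-matched random lists (percentile 100), which argues against a bias that depends on brightness. A linear gradient over slide positions would need -0.10 per position, and within the groups the list moved by 0.062 and -0.0057 per position (mean 0.0282), which argues against it; a step between the groups' positions cannot be told apart from the group. The smallest difference between an overexpression and a control array, 0.16, was 2.59 times the largest between replicates, but with 4 arrays variation between single arrays stays open.

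Genes known to respond to BMP through SMAD proteins were separated from the TGF-beta genes of the same list after the values had been seen. Of 14 tested, 12 were lower in overexpression, with a median of -0.19, and the 13 TGF-beta genes had a median of -0.03. The difference had a permutation p of 0.0037, but genes are not independent replicates. As the split was made with the values in view, neither this p-value nor the percentile below is independent support for it. The BMP genes' median lay at percentile 0 of brightness-matched lists, while camera with an estimated correlation gave p = 0.12. Under the alternatives the median lay between -0.34, with spike-in scaling, and -0.14. Relative to the median of all genes, which spike-in scaling moved to -0.16, it lay between -0.21 and -0.13. A linear gradient over slide positions would need 0.094 per position, and within the groups the median moved by -0.028 in the controls and 0.021 in overexpression (mean -0.00337). Both lie well under the needed slope, which argues against a linear gradient as the whole cause. Lower output of BMP receptor signalling is one hypothesis that would fit these values, and since the genes were picked from the same data it stays open. A gradient or a step between slide positions stays open as well.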
